A study of Arabidopsis thaliana with 33 samples.

How the data were processed

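RNA from Arabidopsis hypocotyl explants was sequenced in 33 libraries, 3 biological replicates in each of 11 groups, per the labels. Explants came from 7-day-old seedlings of Col-0 and of the hy5-2 mutant and were sampled before culture (T0), after 4 days on callus induction medium (CIM, with kinetin at 0.1 mg/L and the auxin 2,4-D at 0.5 mg/L), or after a further 4 or 8 days on shoot induction medium (SIM, 0.15 mg/L IAA and 0.5 mg/L 2-iP) at 22 °C, per the labels' protocols. Low light was 2 and high light 40 µmol per square metre per second, per the labels. Col-0 was sampled in low light at T0 and in both lights in culture, hy5-2 in low light at T0 and in high light in culture, so no hy5-2 culture in low light was available and a test of light within hy5-2 was not possible. High light began with culture, so length of exposure and culture stage go together. Medium and time in culture go together too, as no group stayed on CIM beyond 4 days and none was cultured without it. The labels' protocols name total RNA and a stranded mRNA kit.

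The authors deposited 1 table of raw counts per gene locus, whole numbers with no normalization, in which the column headers carry the name STAR gives to sorted alignments. The submitters' processing notes name STAR, SAMtools, bedtools, edgeR and build TAIR10; their versions, the strand setting, and the treatment of reads with several alignments are not given in the sources used here. The table held 33400 loci, of which 5138 had no count in any library; 77 chloroplast loci were all at 0 and no mitochondrial loci were listed, so organelle genes were not analysed here. The 27261 protein-coding loci held 99.06% of counts. Library totals were 7.24 to 21.18 M reads counted (median 10.06 M). The 10 largest genes took 6.93 to 7.33% of counts in the T0 libraries and 2.84 to 4.13% in the cultured ones. Loci were joined to a TAIR10.1 gene table by locus code (32835 matched, 10662 with a symbol). Intervals of 4227 loci overlap a neighbour, and among 184 genes nested on the opposite strand of a host with at least 1000 counts the median count ratio to the host was 0.412 at a length ratio of 0.323. Reads of overlapping genes are thus of uncertain origin, among them CHS, CASP1, PSAE2, CHLI2, CESA7 and ADH1, as are those of near-identical paralogs (LHCB1.1 to LHCB1.5, RBCS genes).

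Counts were fitted with edgeR 4.0.16 in R 4.3.3: filterByExpr (minimum count 10, minimum total 15, 20842 genes kept), TMM scaling, a quasi-likelihood model with 1 coefficient per group over all 33 libraries, and robust dispersion (common biological coefficient of variation 0.075). Contrasts were 5 between culture stages, 3 between lights in Col-0, 4 between genotypes, 3 of hy5-2 in high light against Col-0 in low light, and 4 differences of the light or genotype effect between SIM and CIM. A gene passed at a two-sided Benjamini-Hochberg adjusted p under 0.05 over all tested genes, and is then said to have risen or fallen; levels are CPM (counts scaled to the TMM-adjusted library total), given as mean ± SD of 3 libraries. Folds against a group without counts are lower bounds against 3 counts over the group. For groups with 1 to 3 counts, levels are given instead.

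Tests of 18 gene lists (374 members, 369 genes; camera p adjusted over the 18 lists of each contrast) used camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), and each was repeated with an estimated correlation. The lists are light signalling, flavonoid and anthocyanin, nuclear photosystem, chlorophyll synthesis, photoprotection, shade and PIF, clock, root meristem and callus, shoot meristem, leaf polarity, cytokinin response, auxin response, cell cycle, xylem, epidermis and stomata, differentiated root, wound and defence, and hypoxia. Of 149 list calls among 270 tests outside the differences of effects, 77 held with an estimated correlation: those for light signalling, flavonoid, photosystem, chlorophyll, photoprotection and clock genes under light at all 3 cultured stages are among them. Of 342 list medians, 10 moved when genes lacking counts were set at their bound (largest move 0.657, flavonoid genes under light at SIM 8 days). Lists, contrasts, alternatives and the rule for naming genes were fixed before the data were examined. Named genes are HY5, HYH and 14 fixed markers at any stage; per contrast the 5 largest rises and 5 largest falls among genes that passed, averaged at least 5 CPM, had all 3 replicates of 1 group above the other, and carried a symbol; and per list up to 2 members per direction with the smallest adjusted p.

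The model was tested on simulated data with known changes in 200 of 20669 genes. At SIM 8 days 85.5% of changed genes were recovered for light (79.3% at 1.5-fold, 92.6% at 4-fold) with 5.5% false calls. For a difference of light effects 67% were recovered. Counts were drawn for independent libraries with the dispersions of the fit. The rates thus leave untested a pairing of replicates, and scaling where many genes differ between the groups compared. The smallest exact permutation p for 3 against 3 libraries is 0.1, so regroupings cannot reach 0.05 there. Alternatives were RLE scaling, DESeq2 1.42.0, no count filter, a stricter filter (1 CPM in 6 libraries), a replicate block, only the compared groups in the model, organelle genes left out (no effect, all at 0), prior count 0.5 and estimated correlation for lists, and each library left out in turn. Overlap of light and genotype effects was set against 20 simulations of the 9 libraries of a stage without any effect. Plots used matplotlib 3.10.9.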

Results

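HY5 (AT5G11260, chromosome 5, 3593380 to 3594992, TAIR10), the light-signalling transcription factor gene mutated in hy5-2, was low in every hy5-2 library. Its level was 1.86 to 3.75 CPM (counts scaled to the library total) in the 12 hy5-2 libraries and 6.53 to 47.5 CPM in the 21 Col-0 libraries. In Col-0, HY5 averaged 8.71 ± 2.16 CPM (mean ± SD, n = 3) at T0, before culture. It averaged 16.9 ± 1.33 CPM in low light and 30.8 ± 3.05 CPM in high light after 4 days on callus induction medium (CIM). After 4 days on shoot induction medium (SIM) the low-light and high-light means were 19.6 ± 4.71 and 44.0 ± 4.84 CPM, and after 8 days 17.3 ± 1.11 and 35.7 ± 5.76 CPM. The hy5-2 means were 2.72 ± 0.714 CPM at T0 and 3.51 ± 0.0198, 3.5 ± 0.267 and 2.65 ± 0.817 CPM at the later stages in high light. Against Col-0 in the same light HY5 fell on the log2 scale by 1.73 ± 0.26 (SE) at T0 (adjusted p = 8.07e-05) and by 3.13 to 3.76 in culture. HYH (AT3G17609, chromosome 3, 6023866 to 6024698), the closest homologue of HY5, followed light and genotype: 2.36 ± 0.584, 12.8 ± 1.13 and 0.585 ± 0.232 CPM at CIM 4 days in Col-0 low light, Col-0 high light and hy5-2 high light, and 4.00 ± 0.533, 27.3 ± 2.25 and 0.415 ± 0.181 CPM at SIM 8 days. At T0 HYH was 4.5 ± 1.29 CPM in Col-0 and 5.98 ± 1.39 CPM in hy5-2, a difference that did not pass (log2 fold change 0.37 ± 0.26 SE, adjusted p = 0.536).

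**Figure D1:**
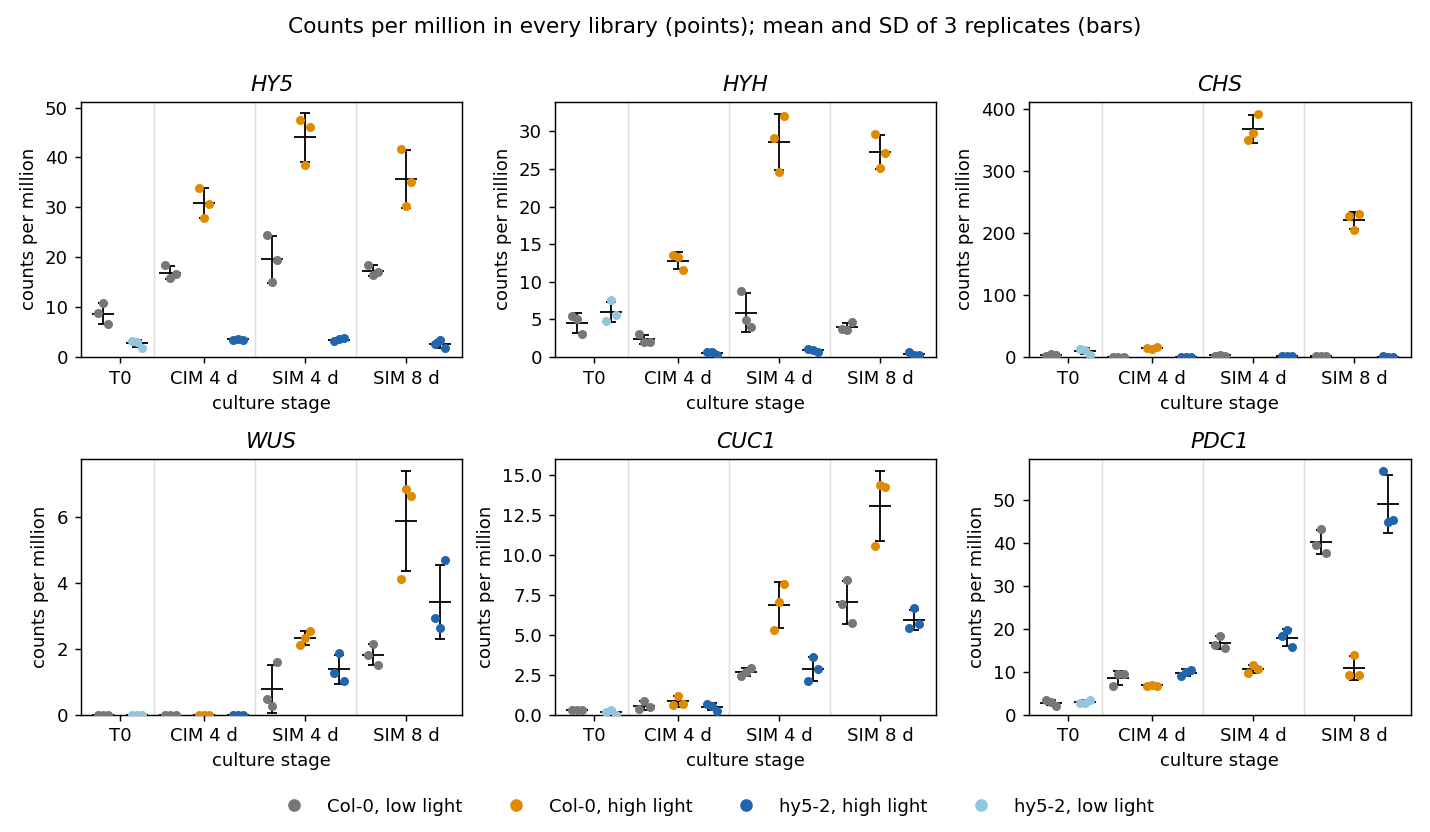
CPM (vertical axes) of HY5, HYH, CHS, WUS, CUC1 and PDC1 at each culture stage; points are single libraries, and bars are the mean and SD of 3 replicates. CHS averages 367.8 CPM in Col-0 in high light at SIM 4 days and 1.06 CPM in hy5-2, while WUS is 0 in every T0 and CIM library.

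Culture stage separated the libraries first. Component 1 of the log2 CPM values held 58.8% of the variance and parted the T0 libraries from all cultured ones; component 2 held 24.2% and parted CIM from SIM. Replicates of a group had Pearson r of 0.985 to 0.994 across genes, which are not independent replicates.

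**Figure D2:**
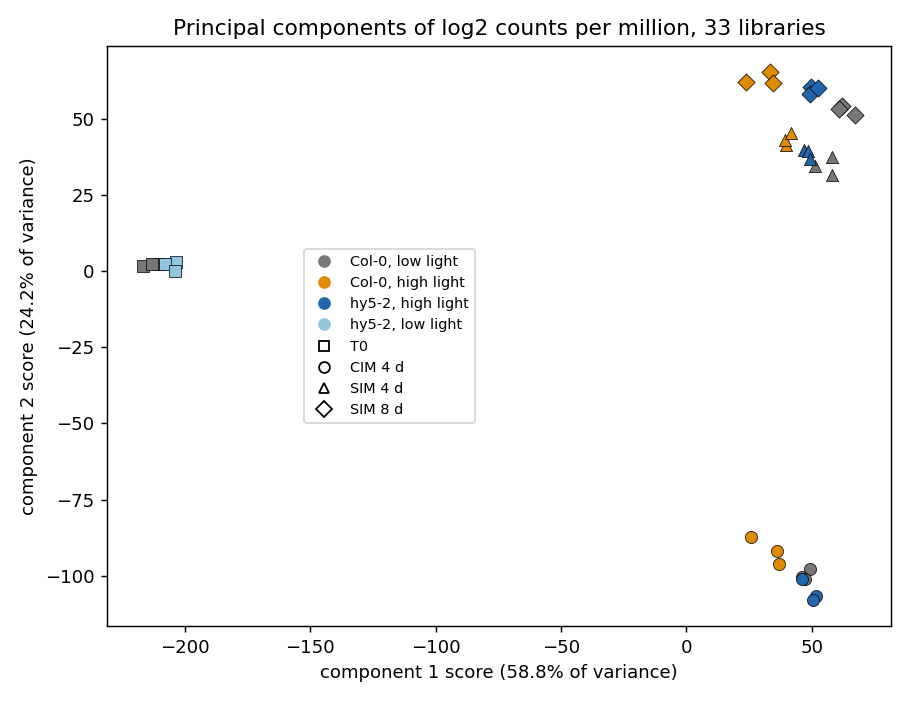
Scores of the 33 libraries on component 1 (58.8% of variance) and component 2 (24.2%) of log2 CPM; symbols give the culture stage and colours the genotype and light. T0 libraries lie apart on component 1, and CIM and SIM libraries lie apart on component 2.

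In low-light Col-0 after 4 days on CIM, root stem cell and cell division genes were higher than at T0 and photosynthesis genes lower. PLT3, a regulator of the root stem cell niche, rose by 6.89 ± 0.11 on the log2 scale (± SE throughout, adjusted p = 8.29e-31), and the auxin-responsive WRKY23 by 6.34 ± 0.12 (adjusted p = 1.32e-29). Against T0 libraries without a count, the embryonic regulator BBM was at least 418-fold higher, PLT2 at least 142-fold and the cytokinin oxidase gene CKX3 at least 2460-fold. The cytokinin synthesis gene IPT3 was at least 856-fold lower and the expansin gene EXPA11 at least 1500-fold lower. STM (AT1G62360, chromosome 1, 23058582 to 23061722), a shoot meristem gene, fell by 4.53 ± 0.36 (adjusted p = 2.24e-13), and WUS was at 0 at both stages. Of 22 root meristem and callus genes measured, 19 rose and 3 fell, the same counts when adjusted over the list alone (median log2 fold change 4.45, camera adjusted p = 1.51e-05). Of 37 cell-cycle genes 36 rose and only CYCD1;1 fell, again the same adjusted over the list alone (median 1.56, adjusted p = 4.19e-11). All 51 nuclear photosystem genes fell, as they did adjusted over the list alone (median -4.23, adjusted p = 5.93e-15, but adjusted p = 0.18 with an estimated correlation). The same holds for the 26 chlorophyll synthesis genes, which all fell (median -1.78, adjusted p = 4.05e-08, and adjusted p = 0.108 with an estimated correlation). Of 25 auxin-response genes 18 rose, 5 fell and 2 did not pass (median 2.06, adjusted p = 0.0055, and adjusted p = 0.211 with an estimated correlation). Markers of other cell types moved with them: all 10 xylem genes fell (median -2.11, adjusted p = 0.000529, and adjusted p = 0.18 with an estimated correlation), and 7 of 8 epidermis and stomata genes fell and 1 rose (median -2.29, adjusted p = 0.0307, and adjusted p = 0.217 with an estimated correlation). Of 9 hypoxia genes 7 rose and 1 fell (median 1.86, adjusted p = 0.0138, and adjusted p = 0.207 with an estimated correlation). Of 10 wound and defence genes 5 rose and 2 fell (adjusted p = 0.293). In all, 16480 of 20842 tested genes passed, 8150 higher and 8330 lower, of which 8869 changed at least 2-fold. Scaling largely sets the median of all genes (-0.004), so this split is relative to it (7971 higher and 8526 lower with RLE scaling). For photoprotection the median (0.61) and mean (0.09) were positive and the camera direction was down (adjusted p = 0.893); for leaf polarity the median (-0.29) and mean (-0.53) were negative and the direction up (adjusted p = 0.633).

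After 4 days on SIM in low light, root meristem genes were lower in Col-0 than at CIM, and shoot meristem, cytokinin and xylem genes higher. The change of medium and the added days in culture were not separated. PUCHI, an auxin-induced gene of lateral root primordia, fell by 5.83 ± 0.20 (adjusted p = 1.3e-20), LBD18 fell by 3.06 ± 0.13 (adjusted p = 1.76e-19) and WOX5 (AT3G11260), the root quiescent centre gene, fell by 4.78 ± 0.25 (adjusted p = 6.27e-16). The cytokinin response regulator ARR15 rose by 2.37 ± 0.11 (adjusted p = 9.55e-19) and CUC1 (AT3G15170, chromosome 3, 5109883 to 5111447), which marks shoot boundaries, by 2.25 ± 0.35 (adjusted p = 2.71e-06). WUS (AT2G17950, chromosome 2, 7808871 to 7810795), the shoot stem cell organizer gene, went from 0 in the CIM libraries to 0.781 ± 0.726 CPM. That mean was at least 8.38-fold higher, but the SD nearly equals it, so the bound is on the mean and not on each library. Against CIM libraries without a count, the extensin genes EXT12 and EXT13 were at least 1260-fold and 458-fold higher and COBL9, of root hair growth, at least 129-fold. Of 22 root meristem genes 13 fell and 3 rose (14 and 3 adjusted over the list alone, median -1.46, adjusted p = 4.48e-05). Of 20 shoot meristem genes 13 rose and 2 fell (13 and 3 adjusted over the list alone, median 0.82, adjusted p = 0.00686), and of 24 cytokinin genes 16 rose and 2 fell (the same adjusted over the list alone, median 1.04, adjusted p = 3.97e-06). Cell-cycle genes fell in 30 of 37 cases (31 adjusted over the list alone, median -0.44, adjusted p = 1.35e-07). All 10 xylem genes rose (median 1.71, adjusted p = 1.2e-08), 7 of 8 epidermis genes fell (median -2.27, adjusted p = 4.48e-05), and of 15 differentiated-root genes 9 rose and 3 fell (median 2.28, adjusted p = 0.000246, and adjusted p = 0.0764 with an estimated correlation). Of 25 auxin genes 18 fell and 2 rose (median -0.47, adjusted p = 0.00168, and adjusted p = 0.166 with an estimated correlation). The 51 photosystem genes had 3 rises and 2 falls (1 fall adjusted over the list alone; adjusted p = 0.518), and their median (0.14) and mean (-0.06) differed in sign. Over all genes, 4487 were higher and 4656 lower.

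Between 4 and 8 days on SIM in low light, shoot meristem and hypoxia genes rose and xylem genes fell. STM rose by 3.31 ± 0.44 (adjusted p = 9.74e-07) and CUC1 by 1.4 ± 0.22 (adjusted p = 1.79e-05), whereas WUS did not pass (1.14 ± 0.45, adjusted p = 0.108). The fermentation gene PDC1 rose by 1.26 ± 0.12 (adjusted p = 9.93e-10). XCP1, a xylem protease gene, fell by 1.83 ± 0.12 (adjusted p = 6.28e-12), from 206.9 to 58.4 CPM. Of 20 shoot meristem genes 5 rose and 15 did not pass (7 rose adjusted over the list alone, median 0.38, adjusted p = 0.000661). Of 9 hypoxia genes 7 rose, the same adjusted over the list alone (median 0.60, adjusted p = 6.02e-06). All 10 xylem genes fell (median -1.73, adjusted p = 4.11e-23), as did 5 of 8 epidermis genes (median -1.73, adjusted p = 6.02e-06) and 7 of 15 differentiated-root genes (median -1.23, adjusted p = 0.000531, and adjusted p = 0.104 with an estimated correlation). Wound and defence genes had 3 rises among 10 (median 0.10, adjusted p = 0.00647, and adjusted p = 0.104 with an estimated correlation). Over all genes, 1386 were higher and 1716 lower.

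In high light the change from CIM to 8 days on SIM was measured in both genotypes. WUS was at least 81.6-fold higher in Col-0 and at least 49.6-fold higher in hy5-2. STM rose by 4.14 ± 0.35 (adjusted p = 6.01e-12) and 3.44 ± 0.41 (adjusted p = 9.77e-09), and CUC1 by 3.95 ± 0.25 (adjusted p = 4.87e-15) and 3.58 ± 0.30 (adjusted p = 5.13e-12). Shoot meristem genes rose in 17 and 15 of 20 cases, with 3 falls in each genotype, counts that were the same adjusted over the list alone (medians 2.00 and 1.88, adjusted p = 5.91e-06 and 0.000369). Root meristem genes fell in 13 and 15 of 22 cases (medians -2.40 and -2.94, adjusted p = 2.68e-05 and 1.11e-05), with 4 rises in each. Epidermis genes fell in 7 of 8 cases in each (medians -3.92 and -4.43, adjusted p = 5.91e-06 and 2.12e-05). Auxin genes had 20 falls among 25 in each, with 3 rises in Col-0 and 1 in hy5-2 (median -1.35 in both, adjusted p = 1.9e-07 and 1.6e-06). Xylem genes rose in 6 and 9 of 10 cases (medians 0.61 and 0.85, adjusted p = 0.0123 and 0.00101, and adjusted p = 0.315 and 0.193 with an estimated correlation). Differentiated-root genes rose in 10 and 9 of 15 with 3 falls in each (medians 1.67 and 2.55, adjusted p = 0.0368 and 0.00225, and adjusted p = 0.315 and 0.155 with an estimated correlation). Photosystem genes rose in 47 of 51 cases in Col-0 (median 1.54, adjusted p = 2.09e-10, but adjusted p = 0.25 with an estimated correlation). They rose in 25 in hy5-2 (median 0.77, adjusted p = 0.00071, and adjusted p = 0.508 with an estimated correlation). Cell-cycle genes had 8 rises and 8 falls in Col-0 (adjusted p = 0.911) and 29 falls and 2 rises in hy5-2 (median -0.36, adjusted p = 8.02e-05, and adjusted p = 0.0873 with an estimated correlation). Cytokinin genes had 14 rises and 3 falls among 24 in Col-0 (14 and 4 adjusted over the list alone, median 0.68, adjusted p = 0.00567, and adjusted p = 0.126 with an estimated correlation) and 16 rises and 3 falls in hy5-2 (median 1.09, or 0.99 with genes lacking counts at their bound, adjusted p = 2.61e-05). Hypoxia genes had 6 rises and 1 fall among 9 in Col-0 (adjusted p = 0.236) and 8 rises in hy5-2 (median 1.56, adjusted p = 8.58e-05). Over all genes, 6178 were higher and 5061 lower in Col-0, and 5800 and 5892 in hy5-2.

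High light at CIM 4 days raised flavonoid, photosystem and photoprotection genes in Col-0. HYH rose by 2.47 ± 0.23 (adjusted p = 1.41e-09), HY5 by 0.87 ± 0.14 (adjusted p = 4.42e-05), the flavonol synthase gene FLS1 by 4.73 ± 0.34 (adjusted p = 5.99e-12) and the chalcone isomerase gene CHI by 2.62 ± 0.15 (adjusted p = 2.72e-14). ELIP1, which protects chlorophyll under strong light, rose by 7.34 ± 0.39 (adjusted p = 5.39e-13). CHS (AT5G13930, chromosome 5, 4488688 to 4490264), the first enzyme gene of flavonoid synthesis, went from 1 count in the low-light libraries to 13.8 ± 1.54 CPM; its interval overlaps a neighbouring gene. Photosystem genes rose in 36 of 51 cases and 15 did not pass (44 rose adjusted over the list alone, median 1.17, adjusted p = 1.43e-38). Flavonoid genes had 9 rises and 2 falls among 23, the same adjusted over the list alone (median 1.00, adjusted p = 1.48e-10), and chlorophyll synthesis genes 9 rises among 26 (15 adjusted over the list alone, median 0.39, adjusted p = 1.62e-12). Photoprotection genes had 7 rises and 1 fall among 13 (median 0.97, adjusted p = 2.3e-07), and light-signalling genes 7 rises among 17 (median 0.16, adjusted p = 5.99e-07). Clock genes had 3 rises and 1 fall among 10, ELF4 rising by 2.50 ± 0.15 (adjusted p = 3.94e-14; list median 0.26, adjusted p = 0.000105). Shade and PIF genes gave adjusted p = 0.925, root meristem genes 0.573 and shoot meristem genes 0.352; the shoot meristem median (0.02) and mean (-0.02) differed in sign. Hypoxia genes fell in 3 of 9 cases (median -0.33, adjusted p = 0.00409, and adjusted p = 0.153 with an estimated correlation). Over all genes, 1072 were higher and 655 lower.

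At SIM 4 days the same groups rose in high light, and shoot meristem genes with them. CHS rose by 7.20 ± 0.25 (adjusted p = 8.22e-16), to 367.8 ± 21.9 CPM, and CHI by 5.20 ± 0.15 (adjusted p = 2.45e-22). ELIP1 was at 0 in low light and at least 611-fold higher in high light. CUC1 rose by 1.38 ± 0.22 (adjusted p = 1e-05) and the boundary gene LSH4 by 2.04 ± 0.29 (adjusted p = 1.63e-06). WUS rose by 1.49 ± 0.41 (adjusted p = 0.0154), from 0.781 to 2.33 ± 0.203 CPM. This call was lost when certain single libraries were left out, which also left fewer replicates. Its adjusted p became 0.0569 without low-light replicate 1 (log2 fold change 1.3), 0.109 without low-light replicate 2 (1.01) and 0.0662 without high-light replicate 3 (1.42), within 0.000218 to 0.109 over all alternatives. Photosystem genes rose in 45 of 51 cases (46 adjusted over the list alone, median 1.86, or 1.81 with genes lacking counts at their bound, adjusted p = 2.34e-46). Chlorophyll synthesis genes rose in 21 of 26 (22 adjusted over the list alone, median 0.83, adjusted p = 1.29e-24), flavonoid genes in 10 of 23 with 2 falls (13 and 2 adjusted over the list alone, median 1.1, adjusted p = 1.34e-12) and shoot meristem genes in 7 of 20 (9 adjusted over the list alone, median 0.41, adjusted p = 0.00244). The haemoglobin gene HB1, induced under low oxygen, fell by 0.77 ± 0.12 (adjusted p = 1.2e-05), and hypoxia genes had 7 falls and 1 rise among 9 (median -0.59, adjusted p = 8.57e-05). Differentiated-root genes fell in 3 of 15 cases (6 adjusted over the list alone, median -0.77, adjusted p = 0.0018, and adjusted p = 0.135 with an estimated correlation). Over all genes, 1895 were higher and 914 lower.

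At SIM 8 days light changed the most genes of the 3 stages compared, and shoot meristem, xylem and hypoxia genes were among them. WUS rose by 1.68 ± 0.35 (adjusted p = 0.000779), to 5.88 ± 1.52 CPM, STM by 1.29 ± 0.26 (adjusted p = 0.000269), CUC1 by 0.88 ± 0.19 (adjusted p = 0.000515) and LSH4 by 2.48 ± 0.23 (adjusted p = 2.63e-10). CHS rose by 7.75 ± 0.30 (adjusted p = 3.16e-15) and PSBS, which dissipates excess light energy, by 6.85 ± 0.31 (adjusted p = 5.18e-15). PDC1 fell by 1.88 ± 0.13 (adjusted p = 2.87e-13), from 40.2 to 10.9 CPM, and the malate channel gene ALMT1 fell by 3.26 ± 0.14 (adjusted p = 1.79e-17). Photosystem genes rose in 47 of 51 cases, the same adjusted over the list alone (median 2.75, or 2.54 with genes lacking counts at their bound, adjusted p = 2.05e-43), chlorophyll synthesis genes in 24 of 26 (median 1.43, adjusted p = 2.96e-23) and flavonoid genes in 12 of 23 with 1 fall (median 2.72, or 2.06 with such genes at their bound, adjusted p = 4.83e-08). Shoot meristem genes had 11 rises and 1 fall among 20 (13 and 1 adjusted over the list alone, median 0.75, adjusted p = 0.000214). All 10 xylem genes rose (median 0.99, adjusted p = 8.08e-08), XCP1 by 1.1 ± 0.12 (adjusted p = 3.53e-08), and 7 of 9 hypoxia genes fell (8 adjusted over the list alone, median -1.02, adjusted p = 8.28e-09). Leaf polarity genes had 7 rises and 1 fall among 10 (median 0.36, adjusted p = 0.0167, and adjusted p = 0.17 with an estimated correlation). Auxin genes had 14 falls and 6 rises among 25 (median -0.36, adjusted p = 0.00403, and adjusted p = 0.172 with an estimated correlation), cytokinin genes 8 falls and 2 rises among 24 (median -0.12, adjusted p = 0.0269, and adjusted p = 0.172 with an estimated correlation) and cell-cycle genes 12 rises among 37 (median 0.14, adjusted p = 0.0107, and adjusted p = 0.207 with an estimated correlation). Wound and defence genes gave adjusted p = 0.405 and epidermis genes 0.522. Over all genes, 3332 were higher and 2416 lower.

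At T0 in low light, hy5-2 differed from Col-0 in PIF and shade genes, flavonoid genes and QQS. QQS (AT3G30720), an orphan gene tied to starch content, was lower by far: 27.1 CPM in Col-0 and 0.389 CPM in hy5-2 (log2 fold change -6.06 ± 0.25, adjusted p = 3.65e-18). PIF4, a transcription factor of stem elongation, fell by 1.14 ± 0.18 (adjusted p = 0.000124) and the clock gene GI by 0.59 ± 0.08 (adjusted p = 1.21e-05). The glutathione transferase gene GSTF12, needed for pigment transport, rose by 2.13 ± 0.34 (adjusted p = 0.000141). DFR, of anthocyanin synthesis, was 0.528 ± 0.523 CPM in Col-0 and 6.2 ± 2.52 CPM in hy5-2 (adjusted p = 0.000903 by edgeR, 0.883 by DESeq2, 2.64e-05 to 0.883 over all alternatives). Of 19 shade and PIF genes 9 fell and 10 did not pass (12 fell adjusted over the list alone, median -0.54, adjusted p = 3.46e-06). Of 23 flavonoid genes 7 rose (11 rose and 1 fell adjusted over the list alone, median 0.32, adjusted p = 5.82e-06). Photosystem genes fell in 6 of 51 cases (28 adjusted over the list alone, median -0.47, adjusted p = 1.16e-07, and adjusted p = 0.323 with an estimated correlation). Over all genes, 412 were higher and 655 lower, 1067 in total. That total changed when single libraries were left out. It was 1726 without Col-0 replicate 1, 384 without Col-0 replicate 2, 604 without Col-0 replicate 3 and 553 without hy5-2 replicate 1.

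At CIM 4 days in high light, the groups that light raised in Col-0 were lower in hy5-2. CHS was at 0 in hy5-2, at least 200-fold lower, and HYH fell by 4.45 ± 0.27 (adjusted p = 4.55e-14), CHI by 3.29 ± 0.15 (adjusted p = 2.1e-17) and ELIP1 by 3.67 ± 0.23 (adjusted p = 4.54e-12). NPY2, of auxin-driven organ formation, rose by 1.79 ± 0.14 (adjusted p = 3.28e-11), and CUC2, a shoot boundary gene, by 1.04 ± 0.16 (adjusted p = 3.28e-05). Photosystem genes fell in 45 of 51 cases (47 adjusted over the list alone, median -2.50, or -2.49 with genes lacking counts at their bound, adjusted p = 2.92e-65). Flavonoid genes fell in 10 of 23 (12 adjusted over the list alone, median -1.32, adjusted p = 6.54e-11), and chlorophyll synthesis genes had 18 falls and 1 rise among 26 (median -0.74, adjusted p = 4.3e-17). Of 37 cell-cycle genes 11 rose (12 adjusted over the list alone, median 0.17, adjusted p = 2.04e-07). Xylem genes fell in 8 of 10 cases (9 adjusted over the list alone, median -0.70, adjusted p = 9.75e-08), and hypoxia genes rose in 6 of 9 (median 0.49, adjusted p = 0.000228). Shoot meristem genes had 2 rises and 6 falls among 20 (adjusted p = 0.271). Over all genes, 1328 were higher and 1907 lower, 3235 in total, against 2139 without Col-0 high-light replicate 1 and 1971 without hy5-2 replicate 3.

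At SIM 4 days in high light, hy5-2 had lower light-raised genes and higher differentiated-root and hypoxia genes. FLS1 fell by 8.56 ± 0.29 (adjusted p = 1.39e-21), CHS by 8.42 ± 0.28 (adjusted p = 2.54e-16) and GUN4, of chlorophyll synthesis, fell by 6.06 ± 0.35 (adjusted p = 4.92e-15). CUC1 fell by 1.32 ± 0.22 (adjusted p = 2.19e-05) and ESR1, a shoot regeneration gene, by 1.42 ± 0.24 (adjusted p = 2.44e-05); WUS did not pass (-0.78 ± 0.39, adjusted p = 0.191). The Casparian strip genes CASP1 and CASP2 rose by 4.08 ± 0.33 (adjusted p = 3.29e-11) and 3.31 ± 0.29 (adjusted p = 2.22e-10), and the cytokinin oxidase gene CKX4 by 2.19 ± 0.26 (adjusted p = 6.47e-08). Photosystem genes fell in 45 of 51 cases (46 adjusted over the list alone, median -3.16, unmoved to 2 decimals with genes lacking counts at their bound, adjusted p = 3.49e-66). Flavonoid genes had 10 falls and 1 rise among 23 (median -1.58, adjusted p = 1.46e-10). Differentiated-root genes rose in 13 of 15 cases, the same adjusted over the list alone (median 1.46, adjusted p = 9.51e-10), hypoxia genes in 8 of 9 (median 0.74, adjusted p = 9.91e-06), and cytokinin genes in 11 of 24 with 2 falls (12 and 2 adjusted over the list alone, median 0.21, adjusted p = 0.00073). Epidermis genes rose in 2 of 8 cases (4 adjusted over the list alone, median 1.02, adjusted p = 0.00838, and adjusted p = 0.12 with an estimated correlation). Shoot meristem genes had 5 falls and 2 rises among 20 (median -0.43, adjusted p = 0.033, and adjusted p = 0.0973 with an estimated correlation). Over all genes, 2167 were higher and 2085 lower.

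At SIM 8 days in high light, shoot meristem and light-raised genes were lower in hy5-2 and hypoxia genes higher. STM fell by 1.06 ± 0.26 (adjusted p = 0.00192), CUC1 by 1.15 ± 0.19 (adjusted p = 2.18e-05), LSH4 by 2.27 ± 0.23 (adjusted p = 1.07e-09) and ESR1 by 0.94 ± 0.22 (adjusted p = 0.00178). WUS averaged 3.42 ± 1.12 CPM against 5.88 ± 1.52 CPM in Col-0, which did not pass (-0.79 ± 0.32, adjusted p = 0.0779). PDC1 rose by 2.17 ± 0.13 (adjusted p = 6.44e-15), HB1 by 2.17 ± 0.13 (adjusted p = 7.05e-15) and the sucrose synthase gene SUS4 by 2.52 ± 0.18 (adjusted p = 7.77e-13). CHS fell by 8.30 ± 0.31 (adjusted p = 1.83e-15). Of 20 shoot meristem genes 11 fell and 9 did not pass (13 fell and 1 rose adjusted over the list alone, median -0.83, adjusted p = 0.000207). All 9 hypoxia genes rose, as they did adjusted over the list alone (median 1.24, adjusted p = 4.22e-12). Photosystem genes fell in 47 of 51 cases, the same adjusted over the list alone (median -3.12, or -2.99 with genes lacking counts at their bound, adjusted p = 1.03e-54), and flavonoid genes had 11 falls and 2 rises among 23 (13 and 2 adjusted over the list alone, median -1.77, or -1.42 with such genes at their bound, adjusted p = 1.53e-07). Cytokinin genes had 9 rises and 1 fall among 24 (median 0.30, or 0.27 with such genes at their bound, adjusted p = 0.000872), ARR5 rising by 0.40 ± 0.06 (adjusted p = 6.9e-06). Cell-cycle genes fell in 14 of 37 cases (median -0.18, adjusted p = 0.000144, and adjusted p = 0.0743 with an estimated correlation), xylem genes in 5 of 10 (median -0.41, adjusted p = 0.002, and adjusted p = 0.199 with an estimated correlation), leaf polarity genes in 5 of 10 (median -0.36, adjusted p = 0.0414, and adjusted p = 0.209 with an estimated correlation), and differentiated-root genes rose in 6 of 15 (median 1.02, adjusted p = 0.000872, and adjusted p = 0.0937 with an estimated correlation). Over all genes, 2113 were higher and 2790 lower.

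**Figure D3:**
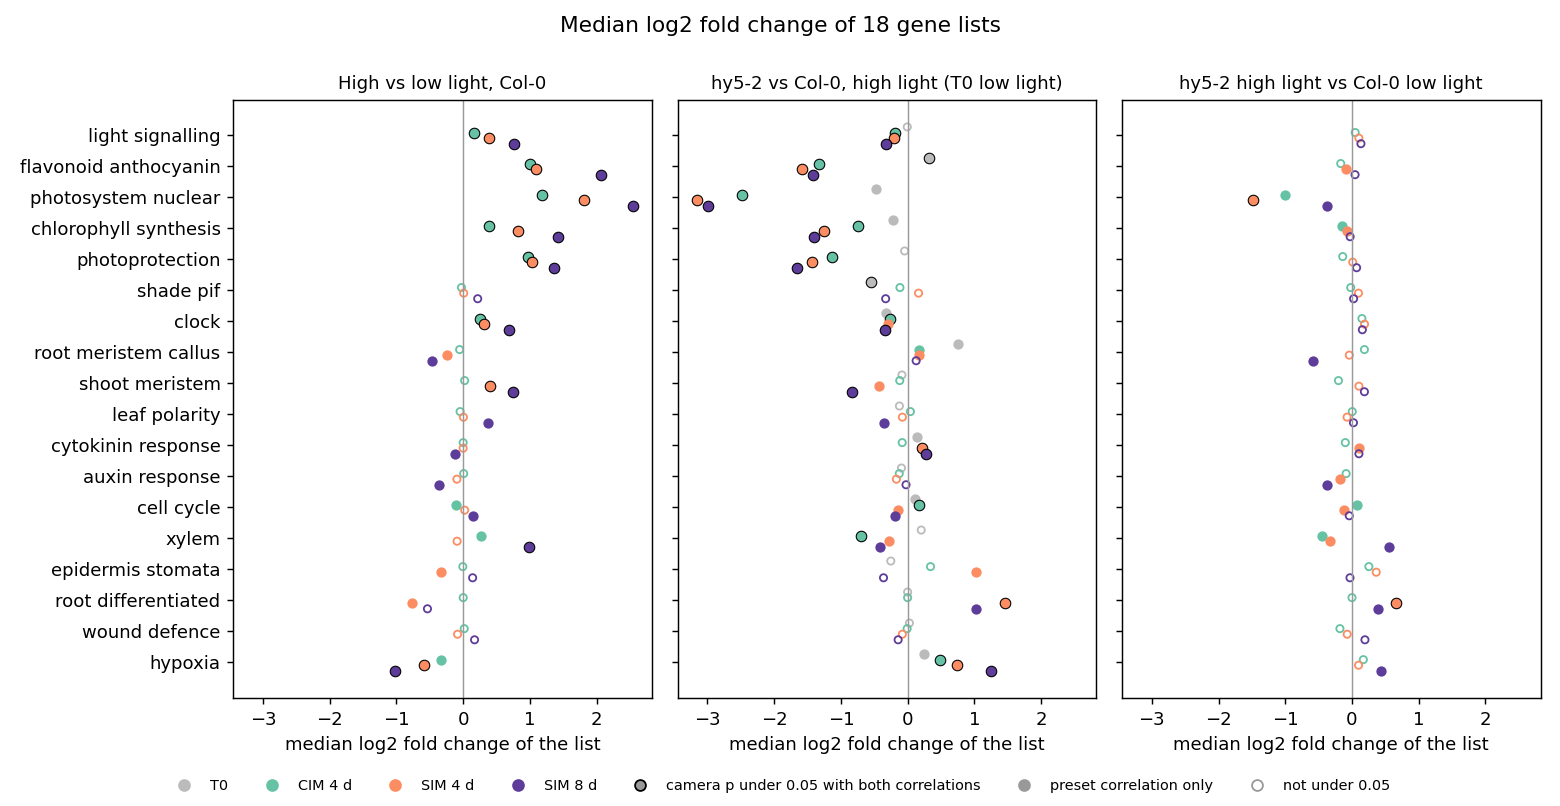
Median log2 fold change (horizontal axes, genes lacking counts at their bound) of 18 gene lists for light, genotype and hy5-2 in high light against Col-0 in low light, with stages in colour; black rims mark camera adjusted p under 0.05 with the preset and with the estimated correlation. Photosystem medians run from 1.17 to 2.54 for light and from -3.16 to -2.49 for genotype at the cultured stages.

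Set against Col-0 in low light, hy5-2 in high light had lower QQS at all 3 stages and lower photosystem genes at SIM 4 days. QQS averaged 14.8 CPM in Col-0 and 0.0236 CPM (1 count) in hy5-2 at CIM 4 days (adjusted p = 1.32e-18) and 17.5 and 0.0623 CPM (2 counts) at SIM 8 days (adjusted p = 8.66e-18), and fell by 6.73 ± 0.30 at SIM 4 days (adjusted p = 2.59e-17). LHCB1.3, an antenna protein gene with near-identical paralogs, fell by 2.93 ± 0.43 at CIM (adjusted p = 7.59e-05) and fell by 4.29 ± 0.52 at SIM 4 days (adjusted p = 3.5e-06). The clock gene PRR5 rose by 1.08 ± 0.13, 1.41 ± 0.12 and 1.4 ± 0.13 (adjusted p = 1.07e-06, 3.91e-10 and 4.3e-09), while the clock gene LHY fell by 1.21 ± 0.17, 1.95 ± 0.17 and 1.09 ± 0.16 (adjusted p = 2.26e-05, 3.71e-09 and 4.8e-05). ESR1 fell by 1.38 ± 0.31, 1.45 ± 0.24 and 1.12 ± 0.22 (adjusted p = 0.00369, 7.31e-05 and 0.000807). WUS and CUC1 did not pass at SIM 4 days (0.71 ± 0.47 and 0.06 ± 0.25, adjusted p = 0.48 and 0.956) or at SIM 8 days (0.89 ± 0.37 and -0.27 ± 0.21, adjusted p = 0.198 and 0.566). Photosystem genes fell in 24 of 51 cases at CIM (29 adjusted over the list alone, median -1.0, adjusted p = 2.52e-25, and adjusted p = 0.438 with an estimated correlation). They fell in 30 at SIM 4 days (36 adjusted over the list alone, median -1.48, adjusted p = 1.37e-41) and in 5 at SIM 8 days (median -0.37, adjusted p = 0.0018, and adjusted p = 0.706 with an estimated correlation). Differentiated-root genes rose in 6 of 15 cases at SIM 4 days (8 adjusted over the list alone, median 0.66, adjusted p = 7.64e-08). Auxin genes fell in 12 of 25 cases at SIM 8 days (15 fell and 2 rose adjusted over the list alone, median -0.37, adjusted p = 3.25e-09, and adjusted p = 0.0535 with an estimated correlation), and xylem genes rose in 5 of 10 (median 0.56, adjusted p = 1.89e-07, and adjusted p = 0.109 with an estimated correlation). Flavonoid genes gave adjusted p = 0.109, 0.0338 (adjusted p = 0.233 with an estimated correlation) and 0.962. Over all genes, 821 were higher and 1381 lower at CIM, 1149 and 523 at SIM 4 days and 826 and 598 at SIM 8 days. Totals were lower with single libraries left out. At CIM, 2202 genes became 1166 without Col-0 low-light replicate 2 and 1174 without hy5-2 replicate 3. At SIM 8 days, 1424 genes became 944 without hy5-2 replicate 1.

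Genes raised by light in Col-0 were largely those lower in hy5-2. Of 1072, 1895 and 3332 light-raised genes at CIM 4, SIM 4 and SIM 8 days, 813, 1404 and 2232 were lower in hy5-2 (75.8, 74.1 and 67%; 98.1, 189.6 and 446 if independent). Of 655, 914 and 2416 light-lowered genes, 163, 564 and 1266 were higher in hy5-2 (24.9, 61.7 and 52.4%, against 41.7, 95 and 244.9 genes if independent). CHS, CHI, HYH and PSBS belonged to the first set at SIM 8 days, PDC1 and HB1 to the second. QQS, set beside light only after its values were seen, had light effects of 0.17 ± 0.12, 0.28 ± 0.12 and 0.36 ± 0.12 (adjusted p = 0.526, 0.141 and 0.0239, the last of which passed) beside 16.6, 17.2 and 22.4 CPM in Col-0 and 0.0236, 0.134 and 0.0623 CPM in hy5-2 in high light. Across 20842 genes, which are not independent replicates, the fold change of low against high light and that of hy5-2 against Col-0 correlated with r = 0.635, 0.75 and 0.778 (covariance 0.211, 0.357 and 0.507). Both share the 3 high-light Col-0 libraries, and 20 simulations without any effect gave mean r = 0.476, 0.454 and 0.519 (highest 0.508, 0.481 and 0.545) and covariance 0.042, 0.04 and 0.056. The 3 shared libraries are too few to give each comparison 2 of its own, so an unknown part of the excess in shared calls belongs to them.

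**Figure D4:**
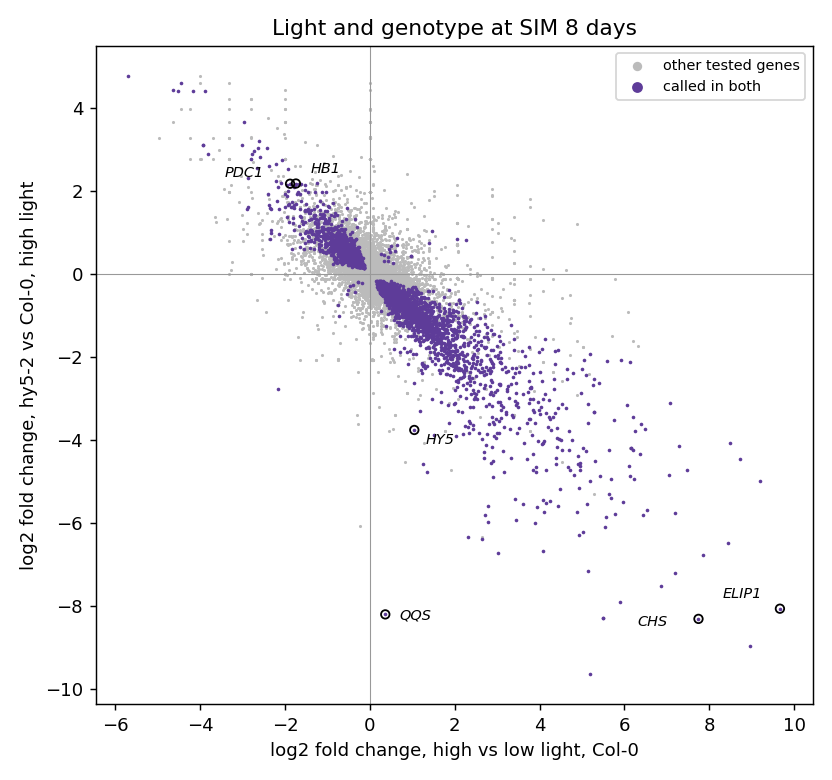
Log2 fold change of each tested gene at SIM 8 days for light in Col-0 (horizontal axis) and for hy5-2 against Col-0 in high light (vertical axis); purple points passed in both comparisons. CHS and ELIP1 lie at the lower right, PDC1 and HB1 at the upper left, and QQS low with a light effect of 0.36.

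Effects were also tested for a difference between SIM and CIM. The light effect on CHI was larger at SIM 4 days by 2.58 ± 0.25 and at SIM 8 days by 2.50 ± 0.30, and that on UGT84A2, which makes sinapate esters that screen ultraviolet light, was larger by 3.19 ± 0.20 at SIM 4 days (adjusted p = 8.34e-13). For ALMT1 and PDC1 the light effect at SIM 8 days was lower than at CIM (differences -2.81 ± 0.17, adjusted p = 4.31e-12, and -1.54 ± 0.20). The hy5-2 effect on UGT84A2 was more negative at SIM 4 days (difference -4.53 ± 0.24, adjusted p = 1.03e-14), and that on PDC1 higher by 1.65 ± 0.20 at SIM 8 days. At SIM 8 days, 41 of 51 photosystem genes had a more positive light effect than at CIM (45 adjusted over the list alone, median difference 1.47, adjusted p = 7.01e-27, and adjusted p = 0.0621 with an estimated correlation). Light effects differed for 289 genes at SIM 4 days and 2218 at SIM 8 days, hy5-2 effects for 1533 and 2688. With the replicate block 520 genes passed in place of 289. The count of 289 also changed when single libraries were left out. It was 168 and 188 without CIM low-light replicates 2 and 3, and 178 and 163 without CIM high-light replicates 2 and 3. It was 149 without SIM low-light replicate 3 and 156 without SIM high-light replicate 1.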

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

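The tests of a linked segment, of library depth and of the slope were chosen before their results were seen, and the other tests of explanations and the regroupings of libraries only after. The next 2 paragraphs give differences of the same effect between SIM and CIM, tested as such with edgeR for genes and camera for lists.

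Light effects differed for 289 genes at SIM 4 days and 2218 at SIM 8 days from those at CIM 4 days. At SIM 4 days the median differences were 0.072 for flavonoid genes (5 of 23 more positive, adjusted p = 3.24e-05), 0.487 for chlorophyll synthesis genes (1 of 26, 14 adjusted over the list alone, adjusted p = 6.09e-12) and 0.355 for photoprotection genes (2 of 13 adjusted over the list alone, adjusted p = 0.0114). At SIM 8 days they were 0.978 for chlorophyll synthesis genes (18 of 26, adjusted p = 1.59e-18), 0.538 for shoot meristem genes (3 of 20, adjusted p = 0.000709; BLH9, a partner of STM, by 1.14) and -0.926 for hypoxia genes (6 of 9, adjusted p = 1.78e-08). Effects of hy5-2 differed for 1533 genes at SIM 4 days and 2688 at SIM 8 days. At SIM 4 days the medians were -0.025 for flavonoid genes (5 of 23, adjusted p = 0.00073), -0.55 for chlorophyll synthesis genes (9 of 26), -0.424 for photoprotection genes (3 of 13), 0.259 for cytokinin genes (6 of 24, adjusted p = 3.6e-05), -0.333 for cell-cycle genes (17 of 37, adjusted p = 1.82e-12) and 1.542 for differentiated-root genes (1 of 15, 5 adjusted over the list alone, adjusted p = 8.81e-10). At SIM 8 days they were -0.424 for cell-cycle genes (23 of 37, adjusted p = 1.75e-12) and 1.211 for hypoxia genes (8 of 9, adjusted p = 4.65e-09; PDC1 by 1.65, ADH1 by 1.27). The flavonoid medians near 0 and means of 0.261 and -0.544 lay apart, with 5 of 23 members passing in each. With the replicate block 520 genes passed in place of 289. The count of 289 became 149 without SIM low-light replicate 3, 156 without SIM high-light replicate 1, 168 and 188 without CIM low-light replicates 2 and 3, and 178 and 163 without CIM high-light replicates 2 and 3.

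For these differences, 25 regroupings of the libraries, the real one included, were counted with edgeR on the compared groups alone. Light or genotype labels were exchanged among the libraries of each stage, and no library changed its stage. At SIM 4 days the light difference called 226 genes and the highest other regrouping 700, with 2 of 25 as large, the real one included. At SIM 8 days 5 of 25 were as large (1710 real, 4455 highest other). For hy5-2, 2 of 25 were as large at SIM 4 days (1554 real, 2401 highest other) and 1 of 25 at SIM 8 days (2352 real, 2325 highest other). The other regroupings as large (1, 4 and 1) each kept or swapped the true groups at 1 stage, as did the one with 2325, and regroupings that mixed both stages called at most 0 genes with edgeR. The effects at single stages thus give these counts their structure, and the regroupings do not decide whether chance can be excluded for any of the 4 differences.

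More genes passed for light at SIM 8 days (5748) than at CIM 4 days (1727), CHI and PDC1 among those with larger effects. Library depth argues the other way: thinned to 7.98 M counts, the 12 libraries gave 4762 and 1144 genes, a ratio of 4.16, against 3.75 unthinned. A smaller spread between replicates at SIM 8 days is excluded by the spread itself (coefficient of variation 0.089 at SIM 8 days, 0.07 at CIM 4 days), and 90.8% of the 2218 genes with a difference (2013) had the larger effect at SIM 8 days. The slope of SIM 8 on CIM 4 effects over the 1727 CIM calls was 0.998 ± 0.018 SE, which met the bound (1 or less) set beforehand for a smaller spread; it lies within 2 SE of that bound, and genes picked by their CIM call have inflated CIM effects, so it decides little. A stronger light response late in culture may explain the pattern, yet length of exposure and culture stage go together here and were not separated.

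Photosystem genes were lower in hy5-2 in high light than in Col-0 in low light at SIM 4 days (median -1.48, 30 of 51 fell). The median was -1.482 with RLE scaling, which moved little in this comparison (1682 genes passed in place of 1672) and so is no test of scaling as a cause. Paralogs outside the list were not checked. Reads shared between list members of the same subunit are not the cause: the 24 without a second list member had a median of -1.351. A need for HY5 in low light too may explain it: at T0 in low light the list had a median of -0.473 in hy5-2, though that call was lost with an estimated correlation (adjusted p = 0.323). It stays a hypothesis, since hy5-2 was not cultured in low light.

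In all 4 comparisons of hy5-2 with Col-0, 108 genes passed in the same direction, 25 higher and 83 lower (1.08 if the comparisons were independent). HY5 is among the lower ones, and some of the 108 overlap and may share reads, such as AT1G48598 and PMEAMT. A chromosome segment linked to HY5 does not account for the 108 genes. Only 3 (2.8%), HY5 itself among them, lay within 2 Mb of HY5. That share was 4.61% (961) among all tested genes (Fisher exact p = 0.491, two-sided). As hy5-2 was the only mutant line, other differences between the lines were not told apart from loss of HY5. For light at SIM 8 days in Col-0, 27.6% of all tested genes passed, and 97 of the 108 (89.8%) passed in the opposite direction. QQS was among them, but its light effect was small beside its fall in hy5-2, a fall already present at T0 in low light. Of all genes that passed for hy5-2 at SIM 8 days, 2232 of 2790 lower and 1266 of 2113 higher ones did so too. The 3 high-light Col-0 libraries at SIM 8 days enter both sides of these counts, so loss of a light-regulated programme stays open as an explanation.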

How the results depend on the processing

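No test in this part was chosen after its result was seen. All 19 counts of passing genes stayed within 1.5 times the reported count in the alternatives that follow. The largest ratios were 1.09 with RLE scaling, 1.17 with DESeq2, 1.16 with no count filter and 1.02 with a stricter filter. With only the compared groups in the model the largest ratio was 1.39 (light at SIM 8 days). The share of higher genes moved by at most 8.1 percentage points. The median of all genes lay within 0.038 of 0, but scaling largely sets this median, so it tests nothing. Leaving out organelle genes tested nothing, as these hold no counts. Labels number replicates 1 to 3. After each group's mean log2 CPM was subtracted per gene, all 3 same-number pairs correlated by 0.1 or more in 7 of 15 comparisons. For light at CIM 4 days (0.16, 0.131 and 0.095) all 6 libraries still correlated best with their own number. For CIM 4 days against T0 in low light 0 libraries did so. The main model leaves this pairing out. With the replicate block all 19 counts were higher, for example 1571 in place of 1067 for hy5-2 at T0. Of these counts 18 stayed within 1.5 times. The difference of light effects between SIM 4 and CIM 4 days gave 520 genes in place of 289, sharing 288. With an estimated correlation 77 of 270 list tests passed in place of 149; the replicate block changed no list call, RLE scaling ended 2 and prior count 0.5 ended 4. Leaving out 1 library gave 384 to 1726 genes for hy5-2 at T0 (384 without Col-0 replicate 2, 604 without replicate 3, 1726 without replicate 1, 553 without hy5-2 replicate 1), and 1971 to 3102 for hy5-2 at CIM 4 days (1971 without hy5-2 replicate 3, 2139 without Col-0 replicate 1). For hy5-2 in high light against Col-0 in low light it gave 1166 to 1910 at CIM 4 days (1166 without Col-0 replicate 2, 1174 without hy5-2 replicate 3) and 944 to 1136 at SIM 8 days (944 without hy5-2 replicate 1). For the difference of light effects at SIM 4 days it gave 149 to 322 (149 and 156 without SIM low-light replicate 3 and high-light replicate 1, 168 and 188 without CIM low-light replicates 2 and 3, 178 and 163 without CIM high-light replicates 2 and 3). Leaving out a library also leaves fewer replicates in its group, so lost power and the weight of a single library were not told apart. The cause was not tested. Of 1028 named-gene calls, 191 were lost without at least 1 library and 54 under another alternative; among 1193 named-gene results, none reversed. The correlation of light and hy5-2 effects stayed above the highest simulated value with RLE scaling, the stricter filter and the replicate block. The simulations were those of the main setting and were not rerun for these alternatives. A run on only genes that passed in either comparison is no test, as the same effects picked those genes.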

Other observations

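All tests of gene families in this part were chosen after the data were seen, as were the regroupings of libraries. The 143 families were formed from gene symbols with at least 10 members tested.

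The HCF and PTAC families of chloroplast biogenesis followed light and hy5-2 at SIM 4 days, and in part at SIM 8 days. Families were not tested for light at CIM 4 days. The light and hy5-2 comparisons of a stage share the high-light Col-0 libraries, so they are not independent. Of 12 HCF genes, which assemble photosynthetic complexes, 9 rose with light at SIM 4 days (median 0.71) and 10 at SIM 8 days (median 0.94), while 8 and 11 fell in hy5-2 (adjusted p with an estimated correlation 0.00426, 0.0144, 0.0115 and 0.00848). Of 14 PTAC genes, parts of the plastid transcription machinery, 12 and 13 rose with light and 13 fell in hy5-2 at both SIM stages (adjusted p with an estimated correlation 0.0151, 0.058, 0.0342 and 0.0325, so light at SIM 8 days did not pass). In hy5-2 neither family passed with an estimated correlation at CIM 4 days (adjusted p = 0.244 for HCF and 0.629 for PTAC) or at T0 (adjusted p = 0.543 and 0.622). Other chloroplast families lost the call with an estimated correlation at SIM 4 days, namely LHCB (adjusted p = 0.255 for light and 0.0626 for hy5-2), TIC (adjusted p = 0.153 and 0.102) and PDE (adjusted p = 0.255 and 0.167), and at SIM 8 days (LHCB 0.134 and 0.0723, TIC 0.355 and 0.3, PDE 0.134 and 0.254). Of 20 B-box (BBX) genes of light signalling, 7 rose and 1 fell with light at SIM 4 days and 10 rose at SIM 8 days, while 1 rose and 4 fell, and 7 fell, in hy5-2 (adjusted p with an estimated correlation 0.0447, 0.058, 0.514 and 0.28), so with an estimated correlation this family passed only for light at SIM 4 days. With RLE scaling the median of all genes lay within 0.028 of 0 in each comparison. That scaling itself sets this median near 0, and the families were not retested with it, so scaling was not tested for them.

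Growth families differed before culture. Of 15 SAUR genes, small auxin-induced genes of cell elongation, 2 fell in hy5-2 at T0 and the family median was -0.60 (adjusted p = 0.000237 with an estimated correlation). Of 24 XTH genes, which remodel cell walls, 7 fell and 1 rose (adjusted p = 0.0137 with an estimated correlation).

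Comparisons of 3 against 3 libraries have 10 regroupings each, too few for a share under 0.05, and in each the real grouping was the 1 with the most genes called by edgeR on the compared groups. For culture the real counts were 15623, 8251, 2502, 9380 and 11547. For light they were 1606, 2188 and 4127, and for hy5-2 914, 2995, 3626 and 3836. The highest other count was 0 in each of these 12. For hy5-2 in high light against Col-0 in low light the real counts were 2194, 1370 and 1551, and the highest others 0, 5 and 0.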
